A study of Mus musculus with 6 samples.

How the data were processed

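Total RNA from frozen samples labelled as brain tissue of mouse embryos at embryonic day 9.5 was sequenced, 3 samples labelled control and 3 labelled as embryos with a neural tube defect after maternal diabetes (DM_NTD). Per the labels' protocols, RNA was extracted with TRIzol and libraries were built with a NEBNext Ultra RNA kit. Whether the counting used strand is not given in the sources used here, so reads of overlapping genes may have been counted for either. The submitters' processing notes name Bowtie 0.12.2 and the genome build mm9. The gene coordinates in the deposited table are those of GRCm38 (mm10): 94.2% of the 15015 genes had the same start and end as in GENCODE M21, and 99.9% overlapped the gene with the same identifier. Coordinates are given here as in the table, on GRCm38.

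The deposited table holds a value per gene and sample in FPKM, made by the authors, and per the file headers the authors' own log2 fold change and unadjusted p-value for DM_NTD against control. The header does not name the unit. It was read from the values: the value multiplied by the merged exon length of the gene was a whole multiple of 1 constant per library, within 0.05 of a read, for 95.97 to 96.55% of the values below 300 reads. Reads (RPKM) and fragments (FPKM) cannot be told apart in this way. The constant gave 65738000 to 72866000 reads per library as the number used in the scaling. In every library the reads recovered in the listed genes exceeded that number. It is therefore not taken as the library's read total, and the cause of the excess was not tested. The tool behind the authors' fold changes and p-values is not given in the sources used here. Genes whose highest value lay below 0.529 FPKM are not in the table used here. A second sheet with a hand calculation for a pair of genes was not used. No per-sample column was left unused.

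Replicates of each group were compared by a chi-square test on the recovered reads of genes with at least 20 reads. Chi-square per degree of freedom ran from 28.5 to 92.7, so no pair of samples agreed within sampling noise, and control replicate 2 stood farthest from the others of its group. Each sample was counted as 1 replicate.

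Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (moderated linear model with a mean-variance trend, without robust shrinkage), with the group as the only term and 4 residual degrees of freedom. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested. P-values are two-sided and Benjamini-Hochberg adjusted over the 12822 genes tested, with a threshold of 0.05. The comparison, the test, the 48 gene lists and the rule for naming genes were fixed before the data were examined. Gene lists were tested with camera of limma at its preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 42 lists with at least 5 tested genes. The 48 lists cover metabolism, chromatin, stress, the cell cycle, signalling, neural tube closure, brain regions, cell types and signs of RNA quality or handling. Each list also has counts of members past the gene test, over all genes and adjusted over the list alone. Another 7 lists were written after the data were seen and serve only in the closing section, except for pluripotency genes, whose levels are also drawn beside the marker lists.

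The naming rule takes Acly, then the 8 genes with the largest rise and the 8 with the largest fall among genes past the test whose groups do not overlap, whose symbols are not placeholders and whose mean is at least the median of tested genes (7.55 FPKM), and in each list up to 4 called members by smallest adjusted p, or up to 2 of the most abundant where none was called. For lists of other cell types the most abundant member was also allowed. Members that make up a count of 5 or fewer in a called list, Tpi1, Aars, Otulin, Mars and Gm45774 as copies or overlaps of named genes, and Pou5f1, Otx2, Hoxb13, Car2, Lyz2 and members of the later lists were named after their values were seen.

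The gene test and camera were tested on simulated data with 12661 genes, 3 against 3 libraries with the spread of the real ones. Of the changed genes, 10.4% were recovered at 1.25-fold, 62% at 1.5-fold, 78.7% at 2-fold and 91.7% at 3-fold. Of 121 calls, 4 were unchanged genes, and 5.21% of the unchanged genes had an unadjusted p below 0.05. Of 42 unchanged lists, camera called 0. The simulated noise was independent between genes, whereas estimated correlations in the real lists reached 0.775. The simulation therefore could not show false list calls that come from correlated genes. Few genes were changed in it, against 40.1% of genes called in the real data, so its recovery rates need not hold there.

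The alternatives were quantile normalization, median centring, no filter, a filter at 5 FPKM in 3 libraries, a pseudocount of 0.1, limma without the trend, limma with robust shrinkage, the replicate number as a block, leaving out each library in turn, camera with an estimated correlation, and fry. Added after seeing the data were the removal of each library's trends on GC content and gene length (loess), protein-coding genes only (11126 tested) and limma-voom on the recovered reads. Tables were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.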

Results

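RNA was sequenced from samples labelled as brain tissue of mouse embryos at embryonic day 9.5, the age at which the neural tube closes. The tissue is given by the labels alone. All 6 libraries held the pluripotency gene Pou5f1 at 1213 FPKM or more. Forebrain list genes present in the table had a median of at most 1.16 FPKM. Those of the neural progenitor list had a median of 7.23 to 8.65 FPKM. The labels give 2 groups of 3 samples. Per the labels, the control group came from normal embryos and the group called DM_NTD here from embryos with a neural tube defect after maternal diabetes. All embryos were labelled wild type. Nothing in the labels says which embryos or litters the replicates came from, so the p-values measure only the spread between these samples, which may be technical. The deposited table listed 15015 genes in FPKM (reads or fragments per kilobase of exon, scaled by library size). The FPKM values of low genes were whole multiples of the value of 1 read. This put the read number used in the scaling at about 65738000, 70994000 and 68330000 for control replicates 1 to 3. For DM_NTD replicates 1 to 3 that number was about 70200000, 72368000 and 72866000. In every library the reads recovered in the listed genes exceeded it, so it is not taken as the library's read total. The cause of this excess was not tested. Across genes, libraries of the same group correlated at 0.985 to 0.991 and libraries of different groups at 0.965 to 0.975 (Pearson, log2 of FPKM + 1). Genes are not independent replicates.

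The series title names ATP citrate lyase, the enzyme that makes acetyl-CoA from citrate in the cytosol, so its gene Acly is reported before the others. Acly (ENSMUSG00000020917, chromosome 11, 100476353 to 100528000, minus strand, GRCm38) stood at 54.1 ± 1.73 FPKM (SD, n = 3) in control and at 78.0 ± 2.21 FPKM (SD, n = 3) in DM_NTD. The control libraries read 52.2, 55.6 and 54.4 FPKM and the DM_NTD libraries 78.3, 80.05 and 75.7 FPKM, so that 3 of 3 DM_NTD values lay above the control values. The log2 fold change was 0.52 with a standard error of 0.053 (limma, adjusted p = 0.000668). The authors' deposited table gave Acly a log2 fold change of 0.43 with an unadjusted p of 1.15e-05.

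The comparison of DM_NTD with control asked which genes differ in embryos with a neural tube defect after maternal diabetes. Txnip, which encodes an inhibitor of glucose uptake, rose from 0.248 ± 0.0631 to 30.0 ± 5.55 FPKM (SD, n = 3). Its log2 fold change was 4.62 (standard error 0.134; limma, adjusted p = 2.55e-05). Ddit3, which encodes the stress transcription factor CHOP, fell from 29.2 ± 3.51 to 5.08 ± 0.9999 FPKM (SD, n = 3), a log2 fold change of -2.32 (standard error 0.136; limma, adjusted p = 0.000168). Of 12822 genes tested, 3109 were higher and 2028 were lower in DM_NTD (limma, adjusted p below 0.05), and without DM_NTD replicate 1 the lower ones were 1335. A fold of at least 2 in FPKM + 1, which understates the change of low genes, was reached by 137 higher and 106 lower genes. The 2 groups did not overlap for 6791 genes, 53% of those tested, where chance gives 10%.

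Among the other genes with the largest rises, Ier3, an immediate early gene, went from 1.69 to 15.9 FPKM with a log2 fold change of 2.64. Ddit4, an inhibitor of mTORC1 signalling, went from 32.9 to 152.6 FPKM with a log2 fold change of 2.16. The glycolytic genes Aldoc (aldolase C) and Ldha (lactate dehydrogenase A) had log2 fold changes of 2.10 and 1.73, and Ldha rose from 65.9 ± 4.56 to 221.4 ± 28.1 FPKM (SD, n = 3). C1ql2, a secreted C1q-like protein gene, had a log2 fold change of 1.77. Tpi-rs11 had 1.74, but it is annotated as a processed pseudogene and may share reads with the glycolytic gene Tpi1, which itself rose with a log2 fold change of 1.29. Exosc6, an RNA exosome subunit gene, was listed at 0.0229, 4.83 and 0.243 FPKM in control replicates 1 to 3 and at 31.3, 36.7 and 31.2 FPKM in DM_NTD replicates 1 to 3, with a log2 fold change of 4.12 and a standard error of 0.604 (4.91 without control replicate 2, 3.66 without control replicate 1). Exosc6 lies wholly within Aars on the same strand and ends at the same base, and Aars did not pass the test (log2 fold change -0.05; limma, adjusted p = 0.599), so how the counting divided reads between them leaves the Exosc6 value uncertain.

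Among the largest falls, Igfbp3, an insulin-like growth factor binding protein gene, went from 22.3 ± 2.25 to 4.67 ± 0.354 FPKM (SD, n = 3), a log2 fold change of -2.04. Mt2, a metallothionein gene, had -2.02, and its span overlaps Gm45774 on the other strand. Adcy1, an adenylate cyclase gene, had -1.57 and Ramp3, a receptor activity modifying protein gene, had -1.53. Snhg1, a long noncoding RNA gene that hosts small nucleolar RNAs, fell from 218.7 ± 11.1 to 79.2 ± 8.32 FPKM (SD, n = 3), a log2 fold change of -1.46. S1pr1, a sphingosine phosphate receptor gene, had -1.45 and Ank, a pyrophosphate transport gene, had -1.41. Ddit3 overlaps Mars, and Ank overlaps Otulin, each on the other strand. The limma adjusted p of these 16 genes lay between 2.55e-05 and 0.00238. On GRCm38, Txnip lies on chromosome 3 from 96557957 to 96561883, Exosc6 on chromosome 8 from 111056339 to 111057664, Ddit4 on chromosome 10 from 59949669 to 59951834, Ldha on chromosome 7 from 46841475 to 46855627, Ddit3 on chromosome 10 from 127290774 to 127296288, Igfbp3 on chromosome 11 from 7206086 to 7213923 and Snhg1 on chromosome 19 from 8723475 to 8726443.

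**Figure D1:**
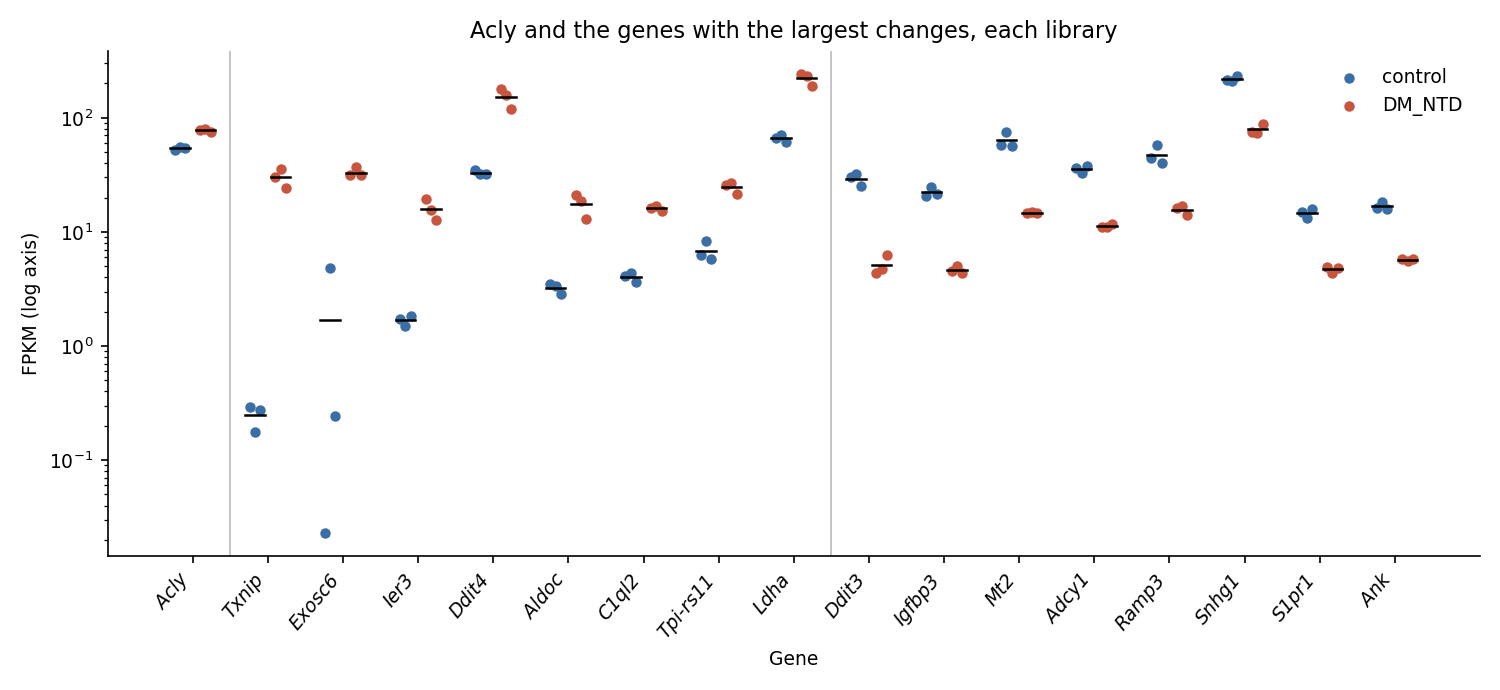
FPKM on a log axis for Acly, the 8 genes with the largest rises and the 8 with the largest falls chosen by the naming rule. Points are single libraries, 3 of control in blue and 3 of DM_NTD in red, and black bars are group means. Acly lies at 52.2 to 55.6 FPKM in control and 75.7 to 80.05 FPKM in DM_NTD, and control replicate 2 holds the highest control value of Exosc6 (4.83 FPKM).

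Across all 12822 genes tested, 40.1% were called, 3109 higher and 2028 lower. Counts of called members in the lists below are to be read against that share. Genes of acetyl-CoA and fatty acid synthesis rose with Acly. Of 22 tested, 18 were higher and 1, Acss1, was lower (19 and 1 adjusted over the list alone), with a median log2 fold change of 0.47. Scd2, a stearoyl-CoA desaturase gene, went from 223.0 ± 1.64 to 438.2 ± 11.3 FPKM (SD, n = 3). Fads2, a fatty acid desaturase gene, had a log2 fold change of 0.78 and Scd1 had 0.74. The list passed camera (adjusted p = 5.85e-06) and did not with an estimated correlation (adjusted p = 0.33). Of 24 genes of cholesterol synthesis and uptake, 15 were higher and 0 lower (16 and 0 adjusted over the list alone; camera, adjusted p = 0.000159; adjusted p = 0.465 with an estimated correlation). An example was Acat2 (log2 fold change 0.58). Of 20 histone acetyltransferase and bromodomain genes, 1 was higher and 7 were lower, the same numbers as adjusted over the list alone, and the list was not called (camera, adjusted p = 0.103). Brd3 was the higher one (log2 fold change 0.44), and Ing4 (-0.49) and Ncoa1 (-0.52) were among the lower ones. Of 17 histone deacetylases and sirtuins, 5 were higher and 2 lower, also adjusted over the list alone (camera, adjusted p = 0.868), with Hdac11 at a log2 fold change of -1.01 and Hdac7 at 0.34. Sirt2, the other lower gene (-0.46), lost its call without DM_NTD replicate 2 (limma, adjusted p = 0.0523). Of 20 Polycomb and H3K27 demethylase genes, 4 were higher and 2 lower (3 and 1 adjusted over the list alone; camera, adjusted p = 0.868), with the histone-binding gene Rbbp7 at 0.51 and Bmi1 at -0.60.

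Genes of glycolysis and of the response to low oxygen rose together. Of 24 glycolysis and glucose transport genes, 16 were higher and 1 was lower (17 and 1 adjusted over the list alone), 5 of them at least 2-fold higher. Slc16a3, a lactate transporter gene, rose from 24.3 ± 2.39 to 63.5 ± 7.26 FPKM (SD, n = 3), and Pfkl, a phosphofructokinase gene, from 19.6 ± 0.906 to 45.4 ± 4.95 FPKM (SD, n = 3). The lower gene was Pfkfb4 (log2 fold change -0.60), which lost its call without control replicate 1 (limma, adjusted p = 0.0672) or control replicate 3 (limma, adjusted p = 0.0664). The list passed camera (adjusted p = 9.59e-06; adjusted p = 0.582 with an estimated correlation). Of 22 hypoxia response genes, 15 were higher and 1 was lower (17 and 2 adjusted over the list alone; camera, adjusted p = 5.85e-06; adjusted p = 0.45 with an estimated correlation). Plod2, a collagen lysyl hydroxylase gene, had a log2 fold change of 1.27, the mitophagy receptor gene Bnip3 had 1.23 and Fam162a had 1.18. Vegfa, a vascular growth factor gene and the lower one, had -0.38 and lost its call without any one of the 3 DM_NTD replicates (limma, adjusted p = 0.0679, 0.0628 and 0.0565 without replicates 1, 2 and 3).

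Nuclear genes of oxidative phosphorylation were higher for 18 of 43 and lower for 1, the same adjusted over the list alone (camera, adjusted p = 0.00752; adjusted p = 0.695 with an estimated correlation). Cycs, which encodes cytochrome c, had a log2 fold change of 0.55 and the ATP synthase gene Atp5h had 0.67. With the trends on GC content and gene length removed, the oxidative phosphorylation list was not called (camera, adjusted p = 0.0516). Of the 13 genes encoded in the mitochondrial genome, 3 were higher and 5 lower (3 and 6 adjusted over the list alone), and the list was not called (camera, adjusted p = 0.265). The higher ones were mt-Nd1, mt-Nd2 and mt-Nd3 and the lower ones mt-Nd4, mt-Nd4l, mt-Atp6, mt-Atp8 and mt-Co1, with mt-Nd3 at a log2 fold change of 0.67 and mt-Nd4 at -0.47. Quantile normalization put mt-Co1 at a log2 fold change of 0, the value it gives any gene with the same rank in all libraries. Under it mt-Nd4, mt-Nd4l, mt-Atp8 and mt-Co1 lost their calls, and mt-Nd4 moved to -0.13. With the GC and length trends removed, mt-Nd4, mt-Atp6 and mt-Atp8 lost theirs (limma, adjusted p = 0.0565, 0.0743 and 0.347). Of 27 antioxidant genes, 12 were higher and 1 lower, the same adjusted over the list alone (camera, adjusted p = 0.0252; adjusted p = 0.582 with an estimated correlation). Prdx1, a peroxiredoxin gene, rose from 131.9 ± 17.6 to 251.2 ± 15.1 FPKM (SD, n = 3), Txnrd1, a thioredoxin reductase gene, had a log2 fold change of 0.82, and Gpx1, a glutathione peroxidase gene and the lower one, had -0.74. The antioxidant call ended without DM_NTD replicate 2 (camera, adjusted p = 0.0516), under quantile normalization (camera, adjusted p = 0.0528) and with the GC and length trends removed (camera, adjusted p = 0.0718).

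Most genes of the list of unfolded protein and integrated stress responses fell. Of 29 tested, 22 were lower and 1, Asns, was higher (24 and 2 adjusted over the list alone), with a median log2 fold change of -0.49. Hspa5, the main chaperone of the endoplasmic reticulum, fell from 203.3 ± 11.5 to 101.7 ± 4.93 FPKM (SD, n = 3). Pdia4, a protein disulfide isomerase gene, had a log2 fold change of -0.78, and Trib3, a stress-induced pseudokinase gene, had -1.38. Asns, the asparagine synthetase gene, had 0.25 and lost its call in 5 of the 6 fits that left out a library (without control replicates 1 and 3 and DM_NTD replicates 1, 2 and 3; limma, adjusted p = 0.0994, 0.136, 0.106, 0.0807 and 0.13), and under 6 other settings (limma, adjusted p = 0.0502 to 0.209). The list passed camera (adjusted p = 2.45e-09) and did not with an estimated correlation (adjusted p = 0.107). Of 85 genes matched as cytosolic ribosomal proteins, 35 were lower and 3 higher, the same adjusted over the list alone (camera, adjusted p = 1.63e-08; adjusted p = 0.582 with an estimated correlation). Rpl10a went from 582.8 ± 17.8 to 411.1 ± 20.8 FPKM (SD, n = 3) and Rpl10 had a log2 fold change of -0.53. The 3 higher ones were Rps27l and Rpl7l1, which encode ribosomal protein-like proteins, and Rpl27, whose call ended without control replicates 1 or 3 or DM_NTD replicates 1 or 2 (limma, adjusted p = 0.0773, 0.089, 0.0768 and 0.0855) and under median centring (limma, adjusted p = 0.0603). Of 18 heat shock genes, 2 were higher and 2 lower, also adjusted over the list alone, and the list was not called (camera, adjusted p = 0.703). Hspa8, the constitutive cytosolic Hsp70 gene, fell from 624.5 ± 45.6 to 239.2 ± 5.66 FPKM (SD, n = 3), and Hspa4 rose with a log2 fold change of 0.53.

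Genes of DNA replication rose. Of 30 S phase genes, 24 were higher and 0 lower, the same adjusted over the list alone, with a median log2 fold change of 0.54 (camera, adjusted p = 1.63e-08; adjusted p = 0.33 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit gene, rose from 16.01 ± 1.23 to 54.7 ± 0.805 FPKM (SD, n = 3), Ccne1, the cyclin E1 gene, from 4.59 ± 0.295 to 16.1 ± 1.305 FPKM (SD, n = 3), and Pcna had a log2 fold change of 0.94. Of 30 mitosis genes, 13 were higher and 2 lower, the same adjusted over the list alone, and the list was not called (camera, adjusted p = 0.228). Ccnb2 had a log2 fold change of 0.69 and Aurkb had 0.52. Of 16 histone genes tested, 7 were higher and 0 lower, also adjusted over the list alone (camera, adjusted p = 0.0237; adjusted p = 0.582 with an estimated correlation). This list was meant for replication-dependent histones, but its clearest member was H1f0 (log2 fold change 1.06), the linker histone H1.0 gene, which is not replication-dependent. Hist1h1c, a linker histone gene, had 1.46. The histone call ended without control replicate 3 (camera, adjusted p = 0.0646) and with the GC and length trends removed (camera, adjusted p = 0.0516). Of 25 folate and one-carbon genes, 9 were higher and 4 lower, also adjusted over the list alone (camera, adjusted p = 0.228), with the glycine decarboxylase gene Gldc at a log2 fold change of 0.86 and Tyms at 0.61. Of 25 p53 target and apoptosis genes, 7 were higher and 2 lower, also adjusted over the list alone (camera, adjusted p = 0.621), with Pmaip1 at a log2 fold change of -0.95. Immediate early genes, a sign of handling as well as of signalling, were higher for 13 of 21 and lower for 4, Klf6, Atf3, Klf4 and Jun (14 and 4 adjusted over the list alone; camera, adjusted p = 0.038; adjusted p = 0.582 with an estimated correlation). Myc had a log2 fold change of 0.90 and Klf6 had -0.92. The immediate early call ended without control replicates 1 or 3 or DM_NTD replicate 3 (camera, adjusted p = 0.0528, 0.0635 and 0.0726). It also ended with a filter at 5 FPKM (camera, adjusted p = 0.108) and with protein-coding genes only (camera, adjusted p = 0.0535). The same held with the GC and length trends removed (camera, adjusted p = 0.0694). The list's mean log2 fold change was 0.38 in the reported fit. In the fits without those replicates it was 0.35, 0.37 and 0.36. It was 0.42 with the filter, 0.38 with protein-coding genes only and 0.28 with the trends removed.

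**Figure D2:**
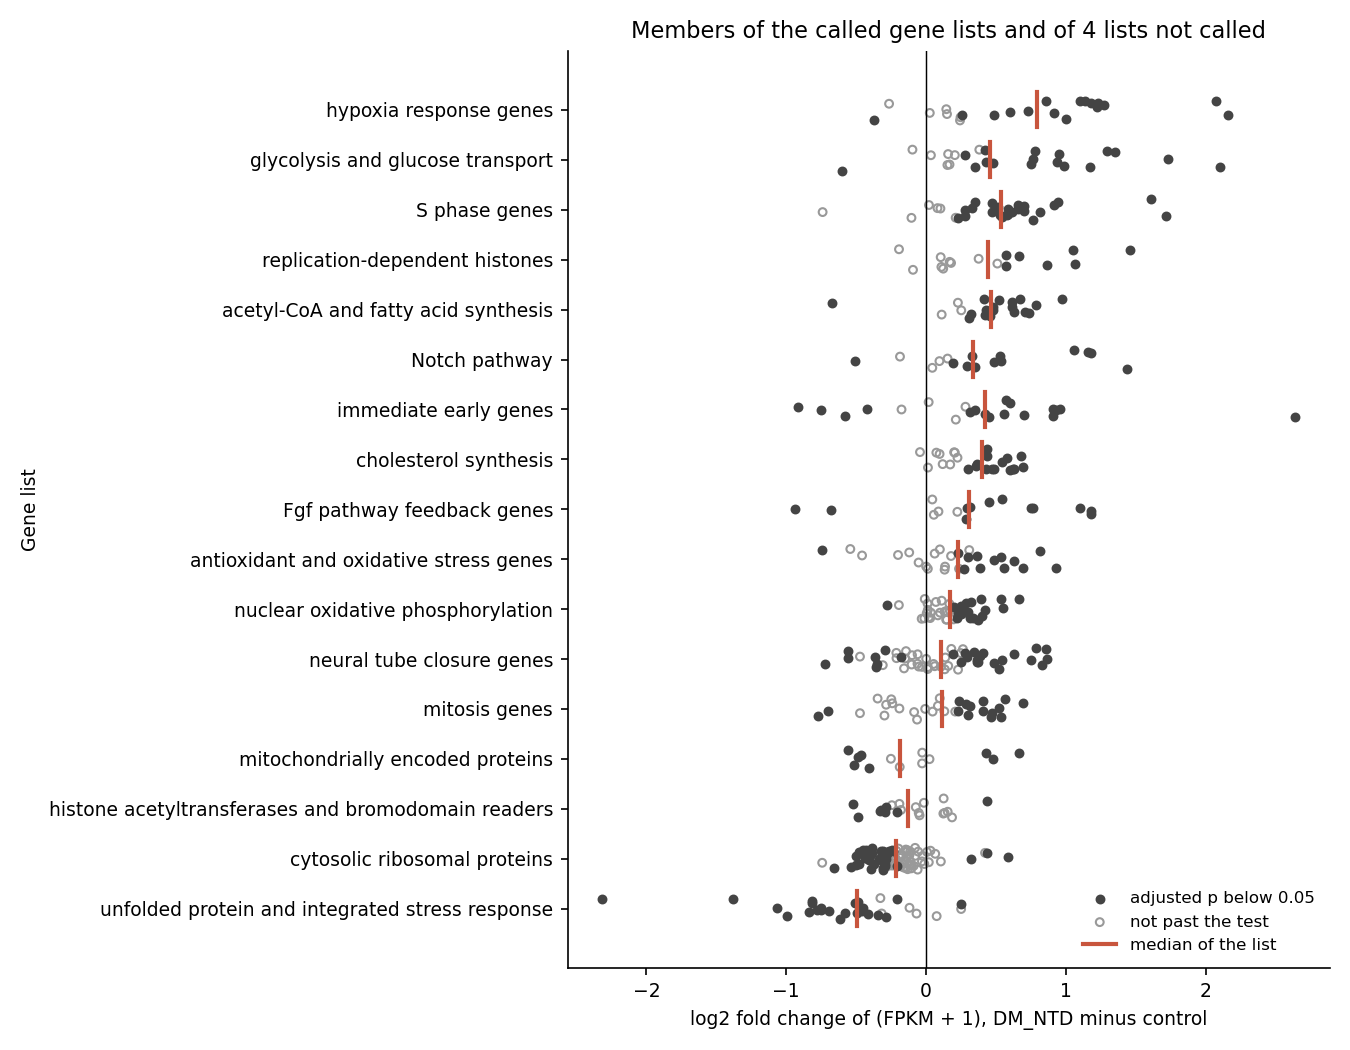
The log2 fold change of (FPKM + 1), DM_NTD minus control, for each tested gene of the 13 called lists and of 4 lists that were not called. Filled points passed limma at an adjusted p below 0.05, open points did not, and red bars are list medians. The medians run from -0.49 for the unfolded protein and integrated stress response to 0.79 for hypoxia response genes.

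Among signalling lists, Notch and Fgf genes rose. Of 16 Notch pathway genes, 11 were higher and 1, Dll1, was lower (11 and 2 adjusted over the list alone; camera, adjusted p = 0.00384; adjusted p = 0.33 with an estimated correlation). Nrarp, a Notch target, had a log2 fold change of 1.43, the ligand gene Dll3 had 1.18, Hes7 had 1.06, and Dll1, another ligand gene, had -0.51. Most of these stood low, with Nrarp at 2.02 ± 0.176 and 7.15 ± 0.401 FPKM (SD, n = 3). With a filter at 5 FPKM the Notch list was not called (camera, adjusted p = 0.107). Its mean log2 fold change was then 0.41, against 0.45 in the reported fit. Of 16 Fgf feedback genes, 10 were higher and 2, Fgfr2 and Fgf18, were lower (11 and 2 adjusted over the list alone; camera, adjusted p = 0.0186; adjusted p = 0.582 with an estimated correlation). Etv5 rose from 39.7 ± 2.40 to 91.1 ± 3.03 FPKM (SD, n = 3) and Dusp6 had a log2 fold change of 1.10. Of 10 Sonic hedgehog pathway genes, 7 were higher and 0 lower, also adjusted over the list alone, with the receptor component gene Smo at 0.45. That list missed the threshold (camera, adjusted p = 0.0664) and passed it under quantile normalization, median centring and no filter (camera, adjusted p = 0.0391, 0.0494 and 0.0415). The lists of Wnt ligands and targets (7 higher and 4 lower of 15), Bmp (3 and 3 of 12), retinoic acid (4 and 3 of 12), insulin and Igf (8 and 7 of 23), imprinted genes (8 and 1 of 20) and cilium genes (5 and 6 of 30) were not called (camera, adjusted p = 0.526, 0.864, 0.771, 0.868, 0.151 and 0.504). Adjusted over the list alone these counts were 7 and 4, 4 and 4, 5 and 4, 8 and 8, 9 and 1, and 5 and 5. Examples were the Wnt inhibitor gene Sfrp2 (log2 fold change 0.83), the Bmp target Id4 (-0.83), the retinol dehydrogenase gene Rdh10 (-0.59), the insulin receptor substrate gene Irs1 (-0.53), the imprinted gene Mest (0.64) and the intraflagellar transport gene Ift88 (-0.55).

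Of 53 tested genes whose loss is known to disturb neural tube closure, 19 were higher and 8 lower (21 and 10 adjusted over the list alone). The list was not called as a group (camera, adjusted p = 0.504). Gldc rose from 17.9 ± 0.835 to 33.1 ± 1.89 FPKM (SD, n = 3). Zic2, a zinc finger gene of the neural plate, had a log2 fold change of 0.83, and Fzd6, a planar cell polarity receptor gene, had -0.72.

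Neural and regional lists were not called as groups. Of 17 neural progenitor genes, 5 were higher and 4 lower (5 and 5 adjusted over the list alone; camera, adjusted p = 0.868). Lin28a rose from 62.7 ± 3.17 to 108.5 ± 4.04 FPKM (SD, n = 3), Sox3 had a log2 fold change of 0.61 and Cachd1 had -0.71. Of 13 early neuron genes, 5 were higher and 0 lower, also adjusted over the list alone (camera, adjusted p = 0.444), with Insm1 at 1.33 and Crmp1 at 0.52. Of 13 mature neuron genes, 4 were higher and 3 lower (4 and 4 adjusted over the list alone; camera, adjusted p = 0.864), with Snap91 at -0.58 and Cplx1 at 0.48. Forebrain (0 higher and 1 lower of 5), midbrain (2 and 1 of 7), hindbrain (2 and 2 of 6) and posterior (2 and 0 of 6) lists were not called (camera, adjusted p = 0.948, 0.703, 0.868 and 0.322). Adjusted over the list alone these were 0 and 0, 2 and 1, 2 and 3, and 2 and 0. The lower forebrain gene was Fezf1, whose call ended without control replicates 1 or 3 or DM_NTD replicates 2 or 3 (limma, adjusted p = 0.104, 0.0851, 0.0996 and 0.0701). Spry1 had a log2 fold change of 0.54, Epha4 had -0.49 and Hoxd13 had 1.22.

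Lists of other cell types of the embryo were not called either. Neural crest (4 higher and 2 lower of 10), extracellular matrix (5 and 3 of 17), somite (3 and 1 of 5), muscle (3 and 1 of 8), erythroid (3 and 0 of 6) and surface ectoderm genes (2 and 2 of 8) had camera adjusted p = 0.682, 0.504, 0.504, 0.601, 0.504 and 0.868. Each of these counts was the same adjusted over the list alone. Twist1 had a log2 fold change of -0.36, the collagen crosslinking gene Loxl2 had 1.22, Tcf15 had 1.54, Myl3 had -1.20, Rhd had 0.57 and Cdh1 had -0.88. Endothelium, macrophages, liver and yolk sac, trophoblast, Y-linked and X inactivation lists had fewer than 5 tested genes (4, 4, 1, 3, 0 and 0) and were not tested. The deposited table held 0 of the 2 X inactivation genes in any library. It held 2 of the 9 Y-linked genes, and neither passed the filter on low values. The signs of the median, the mean and the camera direction disagreed for 6 lists, those of histone deacetylases, neural progenitors, mature neurons, the hindbrain, the Bmp pathway, and insulin and Igf signalling.

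Levels of the marker lists were also compared within libraries. List members absent from the deposited table did not enter the medians. That table held 19 of 23 neural progenitor genes and 8 of 31 posterior ones. It held 7 of 25 forebrain, 8 of 22 midbrain and 10 of 25 hindbrain genes. The median over listed neural progenitor genes lay between 7.23 and 8.65 FPKM over the 6 libraries, and 8 of these 19 genes averaged 10 FPKM or more. Lin28a, the most abundant of them at 85.6 FPKM, also stands in the later list of pluripotency genes. The median over listed forebrain genes lay between 0.93 and 1.16 FPKM over the 6 libraries, that of hindbrain genes between 1.78 and 2.93 FPKM and that of midbrain genes between 3.22 and 3.62 FPKM. The posterior Hox and tail genes had a median between 1.12 and 2.02 FPKM, but 1 of the 8, Hoxb13, averaged 115.3 FPKM. Otx2, the most abundant of the forebrain, midbrain and hindbrain genes, averaged 32.7 FPKM, but it also stands in the later list of pluripotency genes. Pou5f1, which encodes the pluripotency factor Oct4 and was chosen after its values were seen, stood at 1337 ± 141 FPKM (SD, n = 3) in control and 1528 ± 107 FPKM (SD, n = 3) in DM_NTD, among the 37 most abundant listed genes in each of the 6 libraries. Its log2 fold change of 0.20 did not pass the test (limma, adjusted p = 0.162), but did under quantile normalization (0.37; limma, adjusted p = 0.00878) and without control replicate 2 (0.28; limma, adjusted p = 0.0377).

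**Figure D3:**
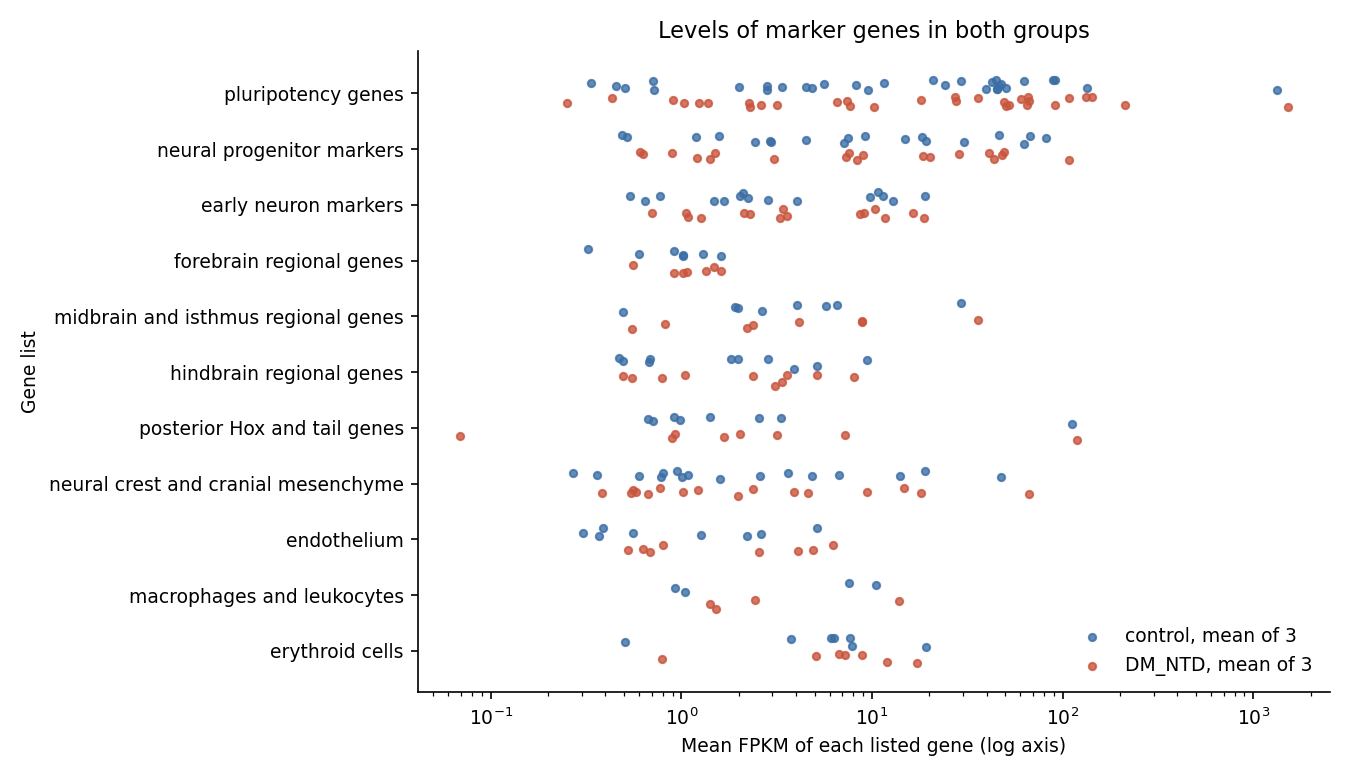
Mean FPKM of each listed gene on a log axis, by marker list, with control means of 3 libraries in blue and DM_NTD means of 3 libraries in red. The list of pluripotency genes was written after the data were seen and the others before. Pou5f1 is the rightmost point, at 1337 FPKM in control and 1528 FPKM in DM_NTD.

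In the authors' deposited table, 569 genes were higher and 543 lower at an unadjusted p below 0.05 with a log2 fold change of at least 1. Of the 243 genes called here with at least 2-fold, 239 were among them. In the other direction, 689 of the authors' genes were tested here, and 655 of those were called at any fold with the same sign. Of the 5137 genes called here at any fold, 5134 had the same sign in the authors' deposited table. For 4536 of them the authors' p, adjusted here by Benjamini-Hochberg, also lay below 0.05. Both comparisons use the same 6 libraries, so this is no independent check. Fold changes here are on the log2(FPKM + 1) scale, which understates the change of low genes: Txnip had 4.62 here and 6.95 in the authors' deposited table. With an estimated correlation in place of the preset 0.01, none of the 42 lists was called by camera, and fry called 26 higher and 4 lower.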

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

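The removal of GC and length trends, protein-coding genes only and limma-voom on recovered reads were chosen after seeing the data. Acly was higher and past the limma threshold under each of the 17 alternatives run for it, with log2 fold changes of 0.41 to 0.54 and adjusted p from 0.000393 to 0.00565. The counts of higher and of lower genes stayed within 1.5 times the reported ones under each alternative, except that leaving out DM_NTD replicate 1 gave 1335 lower genes. Leaving out 1 library at a time gave 2240 to 3387 higher and 1335 to 2700 lower genes, 128 to 160 at least 2-fold higher and 93 to 156 at least 2-fold lower, 9 to 11 lists higher and 2 lists lower, and Acly at 0.50 to 0.54. Counts at 2-fold moved with the scale: 342 higher and 249 lower with a pseudocount of 0.1, and 374 and 276 with limma-voom, since a pseudocount of 1 shrinks the folds of low genes. Lists moved most with the set test: 0 higher and 0 lower by camera with an estimated correlation, 26 and 4 by fry, which tests a list without comparing it with other genes, and 7 higher with the GC and length trends removed, where the cause was not tested. Of called genes, 60.5% were higher, 52.8% under quantile normalization and 51.4% with the trends removed. Of 205 other genes chosen for naming, 178 kept their side of the threshold throughout, 26 lost their call under at least 1 alternative (21 when a library was left out), and no called gene or list reversed. Deviations from the group mean correlated at -0.043, 0.165 and 0.076 between libraries of the same number, so the numbers were not taken to pair samples. The replicate block gave 2969 higher and 2095 lower genes, 140 and 111 at 2-fold, 11 and 2 lists, and Acly at 0.52 (limma, adjusted p = 0.00335). A planned count test on recovered reads was not run, because the deposited values are FPKM and the reads were only recovered from them. In its place limma-voom was run on the same recovered reads, so it shares that limit. In simulated data of this depth and size, with few genes changed, 62% of genes changed 1.5-fold were recovered, so small changes can be missed.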

Other observations

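The 7 lists described here and the tests of the pluripotency, stress and glycolysis patterns were chosen after the results were seen; the counts over other splits of the samples, except that for these 7 lists, were planned. Lysosomal genes and TFEB targets fell: 29 of 38 tested were lower and 3 (Wipi1, Gla and Sgsh) higher, also adjusted over the list alone, with a median log2 fold change of -0.49. Dpp7, a lysosomal peptidase gene, went from 22.5 ± 0.971 to 7.99 ± 0.458 FPKM (SD, n = 3), the sialidase gene Neu1 had a log2 fold change of -0.89, Ctsa had -1.13 and Cd68 had -1.31. The list passed camera, adjusted over the 7 lists, with the preset correlation (adjusted p = 2.66e-10) and with an estimated correlation (adjusted p = 0.0254). That adjustment covers only 7 lists chosen after the data were seen, against 42 for the fixed lists. Over those 42, the unfolded protein and integrated stress response list had an unadjusted camera p of 0.00255 with an estimated correlation and was not called (adjusted p = 0.107). Passing over the 7 lists is therefore no sign of a firmer result than in the fixed lists. The lysosomal list had a camera adjusted p between 6.26e-11 and 1.79e-08 under the other alternatives except limma-voom and fry, which were not run for these 7 lists. Of 25 chaperones and folding enzymes of the endoplasmic reticulum, 16 were lower and 1, Sec61b, higher (20 and 1 adjusted over the list alone; camera, adjusted p = 1.4e-08; adjusted p = 0.0254 with an estimated correlation), and 17 of these 25 also stand in a fixed list. Calr, the calreticulin gene, fell from 227.9 ± 21.8 to 107.9 ± 5.07 FPKM (SD, n = 3) and Derl3 had a log2 fold change of -1.13. The ATF4 list mixes genes of amino acid supply with others such as Trib3, Ddit3 and Ddit4. Its members went both ways, 13 higher and 17 lower of 42 (13 and 18 adjusted over the list alone). It was not called (camera, adjusted p = 0.275), unlike the fixed list of unfolded protein and integrated stress responses at the same preset correlation. Trib3 and Slc6a9 were among the lower (-1.38 and -0.82) and Ddit4 among the higher (2.16).

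Of 20 genes known to respond to glucose through ChREBP or MondoA, 13 were higher and 2, Hbp1 and Slc2a4, lower (14 and 2 adjusted over the list alone; camera, adjusted p = 0.00143; adjusted p = 0.15 with an estimated correlation). Besides Txnip, Klf10 rose from 1.09 to 3.82 FPKM and Arrdc4 had a log2 fold change of 1.10, while the glucose transporter gene Slc2a4 had -0.97. This list was written after Txnip was seen, and 9 of its 22 listed genes stand in fixed lists. Of 16 long noncoding host genes of small nucleolar RNAs, 9 were lower and 2 (Snhg18 and Snhg4) higher, also adjusted over the list alone (camera, adjusted p = 4.78e-05; adjusted p = 0.147 with an estimated correlation). Zfas1 fell from 55.8 ± 1.53 to 24.95 ± 1.252 FPKM (SD, n = 3), and Snhg12 and Snhg6 had log2 fold changes of -1.02 and -0.97. Metallothionein and zinc transport genes were 1 higher and 2 lower of 5, also adjusted over the list alone, and the list was not called (camera, adjusted p = 0.325). Mt1 had -1.20, Mt2 had -2.02 and Slc39a10 had 0.57, and the median (0.065) and mean (-0.49) of this list differ in sign, as do those of the ATF4 list (0.047 and -0.12).

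Pluripotency genes were abundant in all 6 libraries labelled as brain. The table held 31 of the 41 genes of this list, and 17 of them averaged 10 FPKM or more. Pou5f1 led (1213 to 1594 FPKM). It was followed by Lefty1 (135.0 and 213.6 FPKM in control and DM_NTD), Utf1 (88.9 and 143.2 FPKM) and Tdgf1 (91.3 and 133.5 FPKM). Of the 31, 10 stand in fixed lists, 2 of them in that of neural progenitors. Between the groups 16 of the 29 tested were higher and 5 lower (17 and 5 adjusted over the list alone; camera, adjusted p = 0.00505; adjusted p = 0.186 with an estimated correlation).

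Reads from copies of Pou5f1 do not account for the abundance of pluripotency genes, since 9 other pluripotency genes that no fixed list holds also averaged 10 FPKM or more. A minor share of pluripotent cells in brain tissue cannot be told apart from the alternatives by these levels. The median of the 21 pluripotency genes that no fixed list holds was 1.18 to 1.66 times that of 17 neural progenitor markers, with overlapping interquartile ranges in all 6 libraries. That median was 3.55 to 5.12 times that of 39 progenitor and regional genes, of which the regional ones stood near the floor. These medians leave out list members absent from the table, so they cannot decide the question. The table also held 0 of the 2 X inactivation genes and 2 of the 9 Y-linked genes, neither past the filter on low values. Why these genes were absent or low was not tested. Another candidate explanation that stays open is RNA mainly from cells of a pluripotent type, such as a culture or a sample exchanged under the label. Pou5f1 stood within the top 0.246% of listed genes in every library. The table held 8 of 24 endothelial, 4 of 26 macrophage and 7 of 28 erythroid genes. Of these 19, Car2 and Lyz2 averaged 10 FPKM or more. No brain library of known origin was used here for comparison, and since both groups share the pattern the design gives no group to test it against.

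Lower stress response genes stood beside higher glycolysis and hypoxia genes, in lists that camera called at its preset correlation and not with an estimated correlation (adjusted p = 0.107, 0.582 and 0.45). A trend on GC content or gene length as the whole cause is not borne out. With these trends removed the 3 lists kept their directions (highest camera adjusted p 1.46e-05 at the preset correlation). Neither is the scaling of the libraries as the whole cause. Under quantile normalization the mean log2 fold changes were -0.61 for stress response, 0.58 for glycolysis and 0.72 for hypoxia genes (highest camera adjusted p 4.2e-06 at the preset correlation). Because camera compares a list with the other genes, its calls are no test of a shift shared by all genes. A difference in handling before freezing, such as the time without oxygen or glucose, cannot be told apart from an effect of maternal diabetes, because it would follow the groups: immediate early genes went both ways, 13 higher and 4 lower, with a camera adjusted p of 0.582 with an estimated correlation. The effect of maternal diabetes or of the neural tube defect itself stays open and was not tested apart from handling.

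The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Each other split mixes the groups, so the group difference adds to the spread within its sides and partly remains between them. Its counts are therefore no measure of what chance gives. The real split gave 5137 called genes and the highest of the others 1. It gave 243 genes at 2-fold or more and the highest of the others 1. For lists called by camera at the preset correlation, the real split gave 13 of the fixed lists and the highest of the others also gave 13 (2 of the 10 splits reached that count). For the 7 later lists the real split gave 5 and the highest of the others 5 (again 2 of the 10). The split that matched it put control replicates 1 and 3 with DM_NTD replicate 2.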
